A study of Sus scrofa with 3 samples.

How the data were processed

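Kidney tissue of Wuzhishan pigs on a high-fat and high-cholesterol diet was sampled in 3 groups, intact males (IM), castrated males (CM) and castrated males with testosterone replacement (CMT). Per the labels' protocols, total RNA was extracted with TRIzol, RNA of the pigs of a group was pooled in equal amounts, and a library was prepared from each pool with an Ion Torrent total RNA kit. Each description names 3 pigs per pool. The design text instead names an Illumina sequencer and speaks of replicates, and the platform was not settled here; only 3 columns of counts, 1 per group, were used. The dose of testosterone, the time since castration and hormone levels were not given in the sources used here.

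The deposited table holds raw counts per gene, whole numbers that differ in their totals, with gene symbols or numbered identifiers and 7 gene types. FastQC is the only tool that the submitters' processing notes name. The aligner, the counting program, the strand setting, the genome build and the annotation were not given in the sources used here, so no coordinates are printed, and how reads of near-identical genes were assigned is unknown. Such families (metallothioneins, the CYP2C and CYP4A genes, IFITM genes, ribosomal proteins, tRNA) are named with that limit, and antisense or overlapping genes could not be told apart. Of the 34570 genes, 19902 carried a numbered identifier. The RefSeq gene table of assembly Sscrofa11.1 served only to look up symbols for these, and 1556 received a symbol, among them PNPLA3, KCNE1, ATF3 and TRDN, the last on a row typed as miscRNA; 534 more were left as they were because the symbol was already in the table or matched several. Of the compared genes, 3798 had no symbol. A last column without a name held 4 values, each equal to the CM count divided by the CMT count within 1e-06, and was not used.

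Total counts were 16459771 in IM, 18503537 in CM and 13601475 in CMT. A count of 0 allows up to 3 counts, which is 0.181 CPM in IM, 0.159 in CM and 0.227 in CMT. Ribosomal RNA genes took 2.03%, 1.73% and 2.14% of the counts, mitochondrially encoded genes 8.45%, 8.83% and 8.43%, and the 20 most abundant genes 19.5%, 20.1% and 19.8%, in that order. Effective library sizes were set with TMM factors of 1.01, 1.02 and 0.973 from edgeR 4.0.16 in R 4.3.3; no other part of edgeR was used, since 1 library per group leaves no residual degrees of freedom. The median log2 fold of the compared genes was within 0.02 of 0 in each comparison.

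Genes with a mean of at least 1 TMM-scaled CPM over the 3 libraries were compared, 15472 in all, of which 13984 are typed as mRNA. The fold is the ratio of scaled counts, and its exact 95% interval is the Clopper-Pearson interval of the share of counts from a library. A gene was called higher or lower when this interval lay wholly beyond 2-fold. Intervals and floors cover counting error only, because sequenced reads are not independent molecules and because no spread between pigs could be estimated. Log2 folds used a prior count of 2. Against a library with 0 counts the fold is a lower bound, computed with 3 counts in that library; the exact interval, which decided the call, starts below this bound and is given beside it.

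The rule for named genes took, among genes with a symbol, the 12 higher and 12 lower genes with the interval bound farthest from 1 for CM against IM and for CMT against CM. It took 6 and 6 for CMT against IM and 10 and 10 with CM apart from both others, up to 2 higher and 2 lower genes of each list in each comparison, and a fixed set of genes chosen whatever their values, among them SRD5A1, FKBP5, HAVCR1, LCN2 and CYP27B1. Some genes that the rule took are left out of the report. Further members of a list were named after their values were seen where 5 or fewer were called in a direction. The groups, the rule, the alternatives and 40 gene lists of pathways, kidney cell types and other cell types were written before the data were examined. For each list the median log2 fold was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. A list stands apart at or below percentile 2 or at or above percentile 98, which 4% of lists of unrelated genes would do. This ranking describes these libraries and tests no condition. No list had a member at 0 counts, so no median rests on a bound.

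The rule was tested on simulated counts over the 15472 genes, with 50 genes changed at each of several folds in each comparison. At a true fold of 3 it called 35 of 50 genes in CM against IM, 38 in CMT against CM and 44 in CMT against IM, and at a fold of 4 it called 45, 47 and 50. At a fold of 8 it called 50 of 50 in each, at 1.5 it called 0, and it made 0 false calls among unchanged genes. The interval covered the true fold for 95.5% of unchanged genes. Only Poisson counting noise was simulated, with no spread between pigs. These values therefore say nothing of false calls between real pools. Of 200 random lists without change 11 stood apart, and of 50 lists of 30 genes moved by 0.3 on the log2 scale 50 did.

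Comparisons that share the CM library were set beside 100 sets of libraries simulated with no change and beside the overlap of independent lists. Alternatives were scaling by total counts, by upper quartile and by the size factors of DESeq2 1.42.0, no filter or a mean CPM of at least 5, a 99% interval, folds of 1.5 and 4, counts thinned to the smallest library, and removal of the 20 most abundant and the mitochondrially encoded genes. Removal of those abundant genes also scaled libraries by the plain total of the remaining counts, without TMM factors. Lists were also ranked with a prior count of 0.5 and without matching on expression. Counting mRNA genes only, and ranking lists with deposited symbols only, were chosen after seeing the data. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.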

Results

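The study measured kidney RNA of Wuzhishan pigs, a Chinese miniature breed, on a diet rich in fat and cholesterol. Intact males (IM), castrated males (CM) and castrated males given testosterone (CMT) were compared, with 3 pigs in each group. RNA of the 3 pigs of a group was mixed in equal amounts and sequenced as 1 library, so the data hold 3 libraries from 9 pigs and no replicate of any group. The deposited counts sum to 16459771 in IM, 18503537 in CM and 13601475 in CMT. Of the 34570 genes listed, 23521 had a count and 15472 had a mean scaled count of at least 1 CPM, that is, scaled to library size, and were compared. With 1 library per group, no spread between pigs can be estimated and no p-value is given. A gene is called higher or lower when the exact 95% interval of its fold, which covers counting error only, lies wholly beyond 2-fold; the interval follows each fold. The comparisons are of these pooled libraries, and no difference has a replicate check.

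The first comparison asked what differed in the kidney of castrated pigs from that of intact ones. The gene ranked first among those lower in CM acts on steroids. SULT2A1, a sulfotransferase of steroids such as DHEA, gave 5929, 2 and 15219 counts in IM, CM and CMT, and was lower in CM than in IM by 3385-fold (937 to 27954). ESR1, the estrogen receptor alpha, was lower by 16.0-fold (9.91 to 27.4) and HSD17B6, a hydroxysteroid dehydrogenase, by 6.43-fold (5.03 to 8.32), while HSD17B2, which oxidises testosterone and estradiol to their less active keto forms, was higher by 4.21-fold (3.75 to 4.73). CYP2A19, a cytochrome P450, went from 2 counts in IM to 2411 in CM, a ratio of 1056 (292 to 8724). In all, 185 genes were higher and 235 lower in CM than in IM. Of the 29 measured genes of steroid receptors and steroid metabolism, 1 was higher, 4 were lower and 24 were neither, the fourth lower gene being HSD17B4, a peroxisomal enzyme, at 3.44-fold (3.32 to 3.57). As a list they did not stand apart, with a median log2 fold of 0.10 (percentile 96.5) and 17 of 29 above 0. SRD5A1, a steroid 5-alpha-reductase (267, 406 and 297 counts in IM, CM and CMT), did not pass the 2-fold rule. FKBP5, an androgen- and glucocorticoid-responsive chaperone gene, stood at 1.90-fold (1.77 to 2.03) in IM over CM, also short of the rule.

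**Figure D1:**
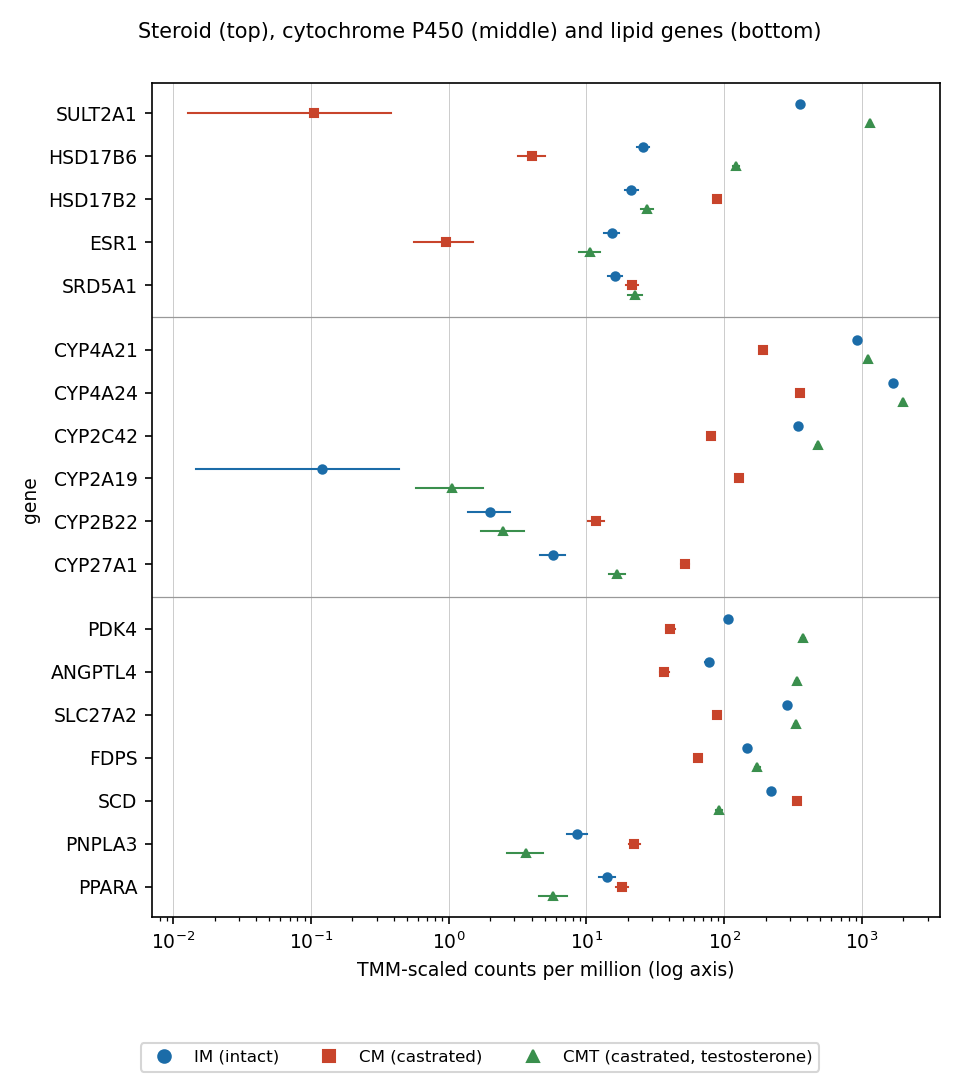
TMM-scaled CPM (log axis) of steroid, cytochrome P450 and lipid genes in the 3 pooled libraries; each symbol is 1 library of 3 pigs and each line its exact 95% Poisson counting interval. SULT2A1 stands at 358 CPM in IM, 0.106 in CM and 1149.9 in CMT, and CYP2A19 at 0.121, 128 and 1.06.

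Enzymes of drug and fatty acid metabolism moved in both directions. Of 45 measured cytochrome P450 and conjugation genes, 5 were higher and 7 lower in CM than in IM, with a median log2 fold of -0.15 (percentile 0.72). The lower ones included CYP4A24 (4.68-fold, 4.55 to 4.80) and CYP4A21 (4.81-fold, 4.64 to 4.99), of the subfamily that hydroxylates fatty acids; these are near-identical copies whose reads the counting may have split or shared. The higher ones included CYP2A19 and CYP27A1, the sterol 27-hydroxylase (9.13-fold, 7.38 to 11.4). The other 3 higher genes were CYP2B22 (5.92-fold, 4.09 to 8.81) and, named after their values were seen, CYP4F2 (2.56-fold, 2.40 to 2.73) and FMO5 (2.24-fold, 2.05 to 2.46). Among 49 measured genes of fatty acid oxidation and PPAR-alpha targets, ACSM5, a medium-chain acyl-CoA synthetase, was the only higher one (23.2-fold, 15.3 to 36.9). The 4 lower ones were the CYP4A pair, HSD17B4 and PDK4, an inhibitor of pyruvate oxidation (2.60-fold, 2.39 to 2.83). Of 46 genes of lipid uptake, storage and efflux, 4 were higher, among them APOC3 (5.60-fold, 4.89 to 6.42) and APOA4 (12.3-fold, 3.92 to 61.8), which code for apolipoproteins, with PLIN4 (3.18-fold, 2.69 to 3.77) and APOA1 (2.47-fold, 2.14 to 2.86). The lower ones there were SLC27A2, a fatty acid transporter and acyl-CoA synthetase (3.21-fold, 3.04 to 3.40), and FABP3 (2.32-fold, 2.06 to 2.61). Cholesterol synthesis genes had a median log2 fold of -0.16 (percentile 1.12), with FDPS (2.25-fold, 2.10 to 2.42) and IDI1 (10.96-fold, 5.71 to 23.6) lower and 24 of 26 neither. That list no longer stood apart under 3 of 11 alternatives. In fatty acid and triglyceride synthesis, PNPLA3, a lipid droplet protein, was higher (2.60-fold, 2.15 to 3.17) and 25 of 26 genes were neither.

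Genes of varied function ranked first in both directions. ALB, AFP and PLG, plasma proteins of the liver, were lower in CM than in IM by 92.9-fold (62.2 to 145), 36.9-fold (16.7 to 102) and 36.5-fold (13.9 to 136). COLQ, the collagen tail of acetylcholinesterase, was lower by 22.8-fold (14.5 to 37.7). A row typed as miscRNA, for which the symbol TRDN was looked up, was lower by 25.7-fold (11.5 to 71.2), and whether it stands for the protein-coding gene is unknown. NELL2 was lower by 20.4-fold (12.9 to 34.4) and S100A11 by 20.04-fold (12.8 to 33.2). DCDC2B, PTCHD2, LRCOL1 and the beta-defensin BD123 had 0 counts in CM and were at least 72.3-, 49.9-, 22.1- and 28.5-fold lower than in IM when 3 counts are put in place of 0; the lower ends of the exact intervals are 58.2, 39.98, 17.4 and 22.6. On the other side, SLC5A8, a sodium-coupled monocarboxylate transporter, went from 2 to 489 counts (ratio 214, 59.0 to 1773). The metallothionein genes MT1A, MT-2B and MT-III, whose products bind zinc and copper, were higher by 42.9-fold (34.4 to 54.0), 23.7-fold (20.9 to 26.8) and 24.7-fold (17.9 to 35.1), with the limit that reads may be shared among these similar genes. DACT2 (20.5-fold, 8.54 to 64.3), CREB3L3, a transcription factor of lipid metabolism (10.3-fold, 7.28 to 15.0), and PLK5 (8.34-fold, 5.19 to 14.2) were higher as well. ASGR1, a subunit of the asialoglycoprotein receptor, had 0 counts in IM and was at least 11.7-fold higher in CM (interval from 9.07). ASGR1, like APOC3, is known from liver, so that genes of that organ went both ways.

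Immune genes divided between CM and IM. Interferon response genes had a median log2 fold of 0.51 (percentile 100), with 53 of 58 members above 0 on the log2 scale, 5 called higher and 0 lower. The 5 were ISG15 (3.20-fold, 2.87 to 3.57), MX1 (2.78-fold, 2.54 to 3.04), CMPK2 (3.001-fold, 2.31 to 3.94) and the similar genes IFITM2 (4.38-fold, 3.58 to 5.39) and IFITM3 (3.57-fold, 2.96 to 4.34), for which shared reads cannot be excluded. Lymphocyte markers had a median log2 fold of 0.34 (percentile 99.93); IGJ, the joining chain of secreted antibodies (6.31-fold, 5.55 to 7.201), and MZB1, a B-cell gene (4.82-fold, 2.81 to 8.79), were higher and 30 of 32 were neither. Of 68 inflammation genes, 2 were higher, C5 (3.16-fold, 2.55 to 3.95) and CXCL12 (2.28-fold, 2.09 to 2.49), and 6 were lower, led by the chemokines CCL4 (6.25-fold, 4.75 to 8.35) and CCL8 (4.97-fold, 3.95 to 6.31). As a list they did not stand apart, with a median log2 fold of 0.04 (percentile 83.9) and 37 of 68 above 0. Ribosomal protein genes had a median log2 fold of 0.27 (percentile 100), and 70 of 71 lay above 0; 3 were called higher, RPL31 (3.66-fold, 3.42 to 3.92), RPS16 (2.12-fold, 2.02 to 2.23) and RPL23A (2.13-fold, 2.01 to 2.27), families with many pseudogene copies.

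Markers of kidney cell types gave small medians, and few of their members passed the rule. Proximal tubule markers had a median log2 fold of 0.06 (percentile 89.6), with SLC22A7 (7.49-fold, 4.59 to 13.0) and SLC5A10 (3.36-fold, 3.07 to 3.67), both transporters, higher and GGT1 lower (2.06-fold, 2.02 to 2.11) among 36. TMEM207 of the loop of Henle was lower in CM (3.25-fold, 2.36 to 4.54), as was KCNE1 of the collecting duct list (3.16-fold, 2.13 to 4.80). SLC26A4, the chloride-bicarbonate exchanger pendrin of intercalated cells, was lower too (4.06-fold, 3.46 to 4.78). Each was the only called member of its list. None of the distal convoluted tubule, podocyte, endothelial or stromal markers passed the rule. Their lists had a median log2 fold of -0.22 (percentile 1.4), a median log2 fold of 0.13 (percentile 98.1), a median log2 fold of 0.05 (percentile 80.3) and a median log2 fold of -0.17 (percentile 1.29), in that order. The distal convoluted tubule, podocyte and stromal lists no longer stood apart under 5, 4 and 2 of 11 alternatives. Cell cycle genes (median log2 fold of -0.42, percentile 0.02) and heat shock and immediate early genes (median log2 fold of -0.33, percentile 0) were low as lists, with 0 of 27 and 0 of 42 called. Circadian clock genes had a median log2 fold of 0.17 (percentile 99.29), with ARNTL, a core clock gene, lower against that direction (2.92-fold, 2.04 to 4.26); the list no longer stood apart after thinning to the smallest library. Adipocyte markers had a median log2 fold of 0.30 (percentile 99.43) over 11 genes, with PLIN4 and PNPLA3 higher; the sign of that median turned when no filter was applied (-0.11) and when symbols looked up for numbered genes were left out (-0.34), and the list no longer stood apart after thinning. No gene of extracellular matrix and fibrosis (81 measured), nuclear oxidative phosphorylation (62), or vitamin D, phosphate and calcium (29) passed the rule. CYP27B1, which activates vitamin D (435, 482 and 682 counts in IM, CM and CMT), and the injury gene LCN2 (253, 317 and 205) were called in no comparison, and HAVCR1, a tubular injury gene, with 1, 1 and 0 counts, was too low to compare.

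The next comparison asked what differed between castrated pigs with and without testosterone. SULT2A1 ranked first among the higher genes, with CMT above CM by a ratio of 10868 (3008 to 89749) on 2 counts in CM. HSD17B6 was higher by 30.2-fold (24.0 to 38.5) and ESR1 by 11.1-fold (6.78 to 19.3), whereas HSD17B2 was lower by 3.23-fold (2.89 to 3.63) and CYP2A19 by 121-fold (71.7 to 221). In all, 285 genes were higher and 171 lower in CMT than in CM. SLPI, a protease inhibitor of secretions, was higher by 22.1-fold (20.4 to 24.1) and ACTC1, the cardiac muscle actin, by 15.6-fold (14.2 to 17.1). COLQ (36.8-fold, 23.6 to 60.7), VGLL2 (75.7-fold, 29.1 to 280.4), ARMC12 (35.4-fold, 19.5 to 71.8) and ALB (24.0-fold, 15.9 to 38.0) were higher too, and DCDC2B, PTCHD2 and BD123 at least 48.6-, 56.2- and 26.7-fold (intervals from 38.8, 45.0 and 21.0). A row named tRNA-Arg, a name that many gene copies carry, had 4, 2 and 86 counts and a ratio of 61.4 (16.5 to 515). Lower genes included SLC5A8 (11.04-fold, 7.68 to 16.4), APRT, an enzyme of purine salvage (14.4-fold, 7.69 to 30.5), IGJ (4.68-fold, 4.13 to 5.31), NPTX1 (6.10-fold, 4.85 to 7.76), GAS2L2 (6.29-fold, 4.79 to 8.399), TMED6 (4.94-fold, 3.89 to 6.34) and CACNA1I, a calcium channel (4.81-fold, 3.83 to 6.11). RPA3, of the replication protein A complex, fell to 3 counts (ratio 13.1, 4.25 to 65.3) and INO80B to 0 (at least 8.87-fold lower, interval from 6.87).

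Genes of fatty acid pathways were among those that differed between CMT and CM. In fatty acid oxidation and PPAR-alpha targets, 9 of 49 were higher and 1 was lower in CMT than in CM, with a median log2 fold of 0.10 (percentile 96.2). The highest were PDK4 (9.19-fold, 8.51 to 9.92) and ANGPTL4, a secreted inhibitor of lipoprotein lipase (9.15-fold, 8.45 to 9.93), and the lower one was PPARA itself, the receptor gene (3.16-fold, 2.46 to 4.11). In fatty acid and triglyceride synthesis, 4 of 26 were lower and 0 higher: PNPLA3 (6.16-fold, 4.56 to 8.48), SCD, the stearoyl-CoA desaturase (3.71-fold, 3.49 to 3.95), and, named after their values were seen, FADS2 (2.88-fold, 2.62 to 3.16) and the regulator SREBF1 (2.48-fold, 2.22 to 2.77). That list had a median log2 fold of -0.02 (percentile 33.4), and neither this list nor that of fatty acid oxidation stood apart. Cholesterol synthesis had a median log2 fold of 0.21 (percentile 99.83), with FDPS called higher (2.69-fold, 2.51 to 2.88) and 25 of 26 neither. In lipid uptake, storage and efflux, 4 were higher, led by SLC27A2 (3.71-fold, 3.51 to 3.93) and the lipase gene LIPE (3.52-fold, 2.53 to 4.95), and 3 lower, led by PLIN4 (3.88-fold, 3.19 to 4.76) and APOC3 (3.63-fold, 3.21 to 4.11). Of the P450 and conjugation genes 9 were higher, among them CYP2C42 (5.98-fold, 5.65 to 6.33) and CYP4A21 (5.72-fold, 5.51 to 5.93), and 4 lower, among them CYP2A19 and CYP2B22 (4.73-fold, 3.27 to 7.04); the CYP2C and CYP4A genes have close copies that may share reads. PCK1, the gene of the rate-limiting enzyme of gluconeogenesis, was higher (2.54-fold, 2.52 to 2.56) among 3 higher and 0 lower of 45 glucose genes, PDK4 being another.

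Among stress and immune lists, those of heat shock and immediate early genes and of lymphocyte markers stood apart between CMT and CM. Those of inflammation (percentile 75.6) and endoplasmic reticulum stress (percentile 96.5) did not. Heat shock and immediate early genes had a median log2 fold of 0.56 (percentile 100), with 36 of 42 above 0; the 5 called higher were ZFP36 (7.76-fold, 6.06 to 10.05), FOS (2.88-fold, 2.62 to 3.17), ATF3 (2.45-fold, 2.24 to 2.67), EGR1 (2.55-fold, 2.36 to 2.75) and BAG3 (2.20-fold, 2.08 to 2.33). Genes of this kind can respond quickly to handling of tissue. Lymphocyte markers had a median log2 fold of -0.41 (percentile 0); IGJ, CD247 (2.79-fold, 2.26 to 3.48) and CD79A (4.73-fold, 2.24 to 11.5) were lower. Ribosomal protein genes had a median log2 fold of -0.27 (percentile 0), with 70 of 71 below 0 and 0 called. In CMT against IM they did not stand apart (median log2 fold of -0.01, percentile 14.6), so CM was the pool that differed. Kidney injury genes had a median log2 fold of 0.15 (percentile 99.42), a call lost after thinning. S100A11 (16.8-fold, 10.6 to 28.0) and CD44, an adhesion receptor (6.09-fold, 5.65 to 6.58), were higher. Both had been lower in CM than in IM, CD44 by 3.56-fold (3.29 to 3.85), and neither was called in CMT against IM. The injury list did not stand apart in CM against IM (median log2 fold of -0.09, percentile 9.08), with 0 higher and 2 lower. S100A12, a granulocyte protein, was higher by 24.9-fold (10.3 to 78.5). The androgen response list had a median log2 fold of 0.12 (percentile 98.4), with ELL2 higher as the only called gene of 40 (3.23-fold, 2.79 to 3.74). FKBP5 fell short of the rule at 1.95-fold (1.81 to 2.10). The list no longer stood apart under 2 of 11 alternatives. It did not stand apart in CM against IM (median log2 fold of -0.04, percentile 28.7), where ELL2 (2.69-fold, 2.33 to 3.11) and IDI1 were lower and 0 were higher, nor in CMT against IM (median log2 fold of -0.01, percentile 40.5), where 0 were called. The transporters SLCO4C1 (4.21-fold, 3.68 to 4.83) and SLC22A10 (2.78-fold, 2.57 to 3.01) and the exchanger SLC26A4 (2.87-fold, 2.41 to 3.42) were higher, and SLC22A7 lower (2.995-fold, 2.07 to 4.43). Distal convoluted tubule markers had a median log2 fold of 0.21 (percentile 98.5), a call lost under 3 of 11 alternatives, while interferon response genes had a median log2 fold of 0.06 (percentile 90.6) with 0 of 58 called.

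The last comparison asked how far the pigs given testosterone lay from intact ones. Fewer genes differed, 140 higher and 92 lower in CMT than in IM. SAL1, the salivary lipocalin that carries pheromones in the boar, ranked first by its interval, with 2721, 5352 and 39149 counts in IM, CM and CMT, and was higher by 18.0-fold (17.3 to 18.7). CREB3L3 (23.8-fold, 17.0 to 34.5), ACSM5 (18.7-fold, 12.2 to 29.8), PLK5 (18.9-fold, 11.9 to 31.8) and MT1A (13.1-fold, 10.5 to 16.7) were higher, and ASGR1 at least 20.8-fold (interval from 16.3). NELL2 (45.3-fold, 20.6 to 124), SFRP2, a secreted regulator of Wnt signalling (5.73-fold, 4.41 to 7.55), PLG (6.395-fold, 3.79 to 11.5), CYP1A1 (5.51-fold, 3.67 to 8.58) and ALB (3.86-fold, 3.47 to 4.31) were lower, and INO80B at least 12.5-fold (interval from 9.79). SULT2A1 and HSD17B6 were higher in CMT than in IM as well, by 3.21-fold (3.12 to 3.31) and 4.70-fold (4.22 to 5.24), with 0 lower among 29 steroid genes. Interferon response genes had a median log2 fold of 0.76 (percentile 100), with 8 of 58 higher and 0 lower, led by ISG15 (4.20-fold, 3.77 to 4.69) and MX1 (3.18-fold, 2.90 to 3.49). Macrophage and granulocyte markers moved with them (median log2 fold of 0.31, percentile 99.99), with S100A12 (15.5-fold, 7.23 to 39.8) and the scavenger receptor MSR1 (3.05-fold, 2.03 to 4.70) higher among 27, while lymphocyte markers had a median log2 fold of -0.00 (percentile 61.2).

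Fatty acid oxidation and PPAR-alpha targets had a median log2 fold of 0.09 (percentile 99), with ACSM5, ANGPTL4 (4.38-fold, 4.12 to 4.67) and PDK4 (3.53-fold, 3.35 to 3.73) higher and 0 lower, and SCD was lower (2.37-fold, 2.22 to 2.53). P450 and conjugation genes had a median log2 fold of 0.14 (percentile 99.92); GSTA1 (2.74-fold, 2.60 to 2.88), CYP27A1 (2.95-fold, 2.31 to 3.80) and CYP2A19, on 2 counts in IM (ratio 8.76, 2.01 to 79.4), were higher and CYP1A1 was lower. The sign of that median turned when no filter was applied (-0.0093), and the list no longer stood apart without the most abundant genes. Heat shock and immediate early genes had a median log2 fold of 0.24 (percentile 100), with ZFP36 (5.56-fold, 4.43 to 7.03) and FOS (2.26-fold, 2.06 to 2.48) higher. Kidney injury genes had a median log2 fold of 0.12 (percentile 99.67), with MMP7, a matrix protease, higher as the only called one of 38 (2.77-fold, 2.24 to 3.44). MMP7 and AGRN (2.50-fold, 2.05 to 3.07), both higher, were the only called genes of 81 in the matrix list. Podocyte markers (median log2 fold of 0.26, percentile 100) and erythrocyte markers (median log2 fold of 0.45, percentile 98.8, 7 genes) were high as lists, and cell cycle genes (median log2 fold of -0.27, percentile 0.51) and stromal markers (median log2 fold of -0.18, percentile 0.07) low, with 0 genes called in these 4 lists. The lists that stood apart numbered 12, 7 and 10 of 40 in the comparisons of CM with IM, CMT with CM, and CMT with IM. By chance 1.6 would, if the genes within a list varied independently, as those of the random lists do. Genes of a list that vary together raise that number for any difference between pools.

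**Figure D2:**
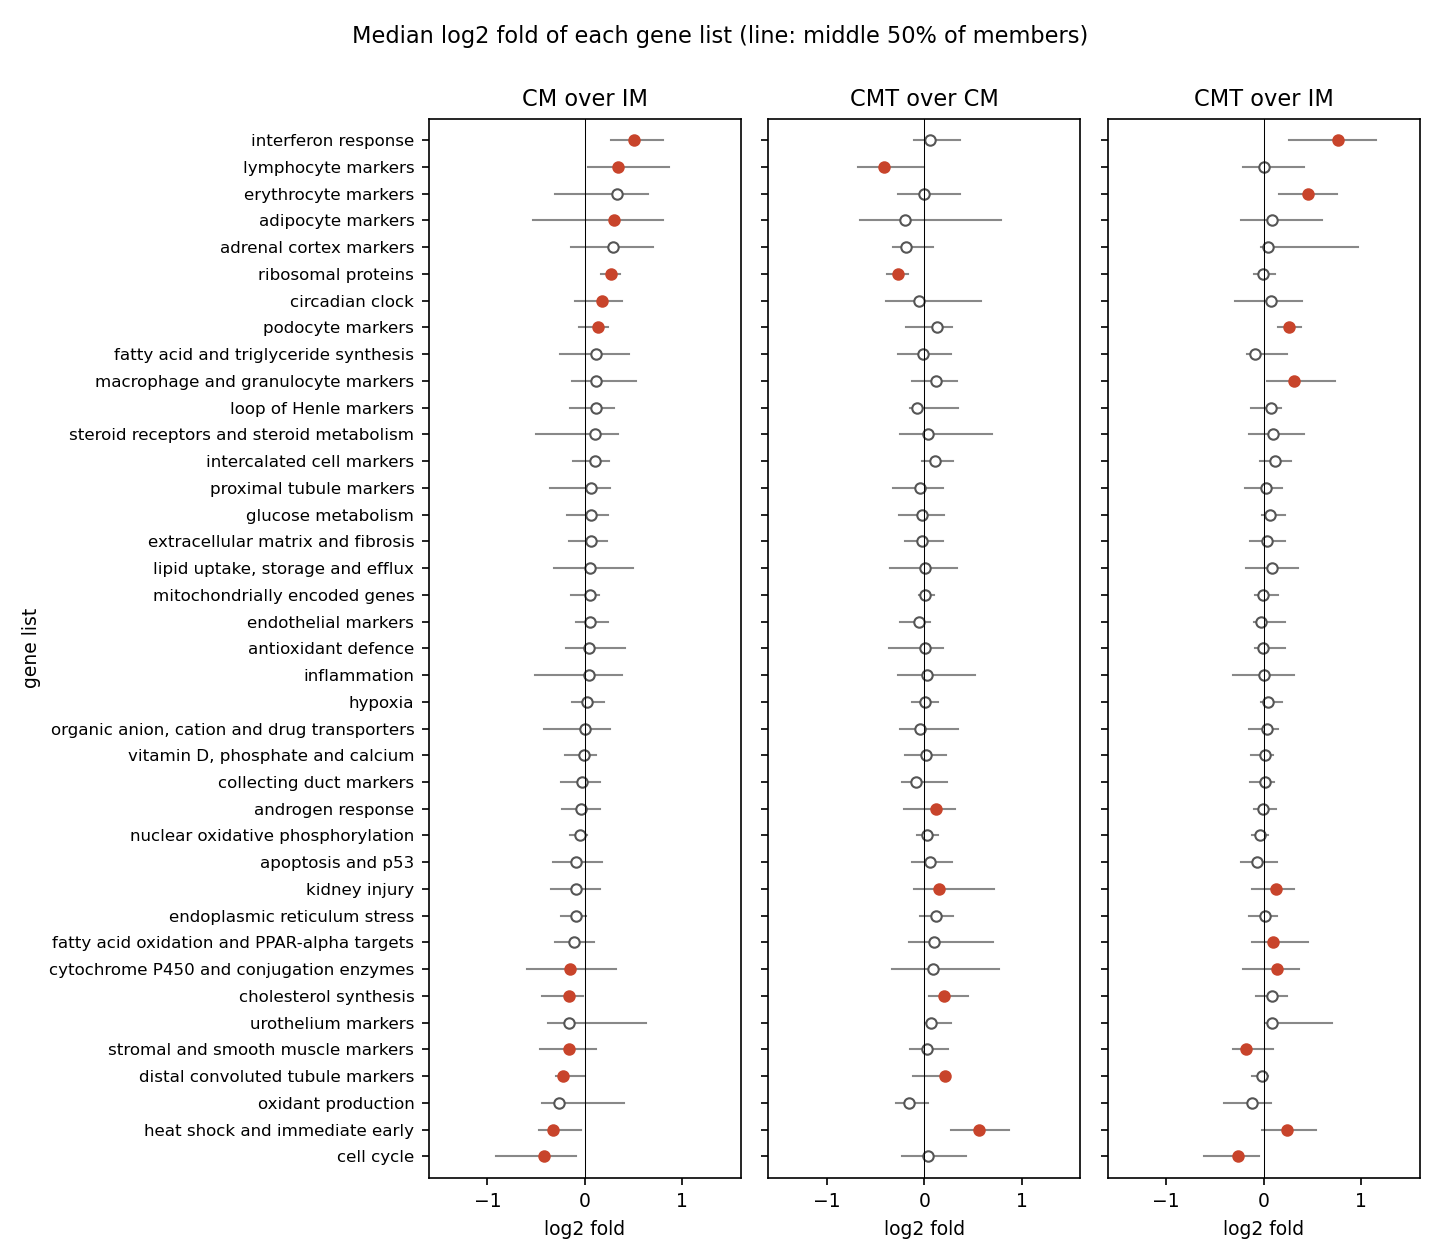
Median log2 fold (points) and middle 50% of members (lines) of all but 1 of the 40 gene lists in the 3 comparisons; filled points lie at or below percentile 2 or at or above percentile 98 of 10000 random lists matched on expression. The interferon response median stands at 0.51 in CM over IM, 0.06 in CMT over CM and 0.76 in CMT over IM.

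The castrated pool stood apart from both others in more genes than either of those did. CM was lower than both in 147 genes and higher than both in 79. IM stood apart from both others in 80 genes (25 higher, 55 lower) and CMT in 81 (44 higher, 37 lower). For CMT the balance of directions turned under total counts (36 higher, 41 lower) and without the most abundant genes (40 higher, 44 lower). Both of these settings scaled by plain totals. The balance held under upper-quartile factors (44 higher, 37 lower) and DESeq2 size factors (47 higher, 34 lower). The genes lowest in CM against both were SULT2A1, PTCHD2, DCDC2B, BD123, ALB, COLQ, AFP, VGLL2, ARMC12 and S100A11. Those highest were CYP2A19, SLC5A8, IGJ, APRT, DACT2, TMED6, CYP2B22, APOC3, ANXA13 and MT1A. ANXA13, an annexin of epithelial cells, for example had 195, 802 and 154 counts in IM, CM and CMT. Of the 235 genes lower in CM than in IM, 147 were higher in CMT than in CM and 0 were lower, and CMT lay nearer to IM than to CM in 192 (81.7%). Of the 185 higher in CM than in IM, 79 were lower in CMT than in CM and 2 were higher, and CMT lay nearer to IM in 108 (58.4%). Independent lists of these sizes would share 4.33 and 2.04 genes. For the shares nearer to IM no value without change was computed, and these genes were chosen for a difference between CM and IM.

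Both of these comparisons use the CM library, so its chance values enter each, and with 1 library it cannot be split; part of the excess may come from it. The simulated libraries hold counting noise only and no spread between pigs, so any difference between pools, whatever its cause, exceeds them. In 100 simulated sets of unchanged libraries, no comparison had more than 1 called gene. The covariance over genes of each library's log2 folds over the other libraries was 0.25 for CM, 0.12 for IM and 0.12 for CMT, where unchanged libraries gave 0.02, 0.02 and 0.03. The correlation across genes of the folds of CM over IM and CM over CMT was 0.68, against 0.42 in a simulated unchanged set, and genes are not independent replicates. After subtraction of this counting noise, CM carried 54.7% of the sum, IM 23.2% and CMT 22.1%.

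**Figure D3:**
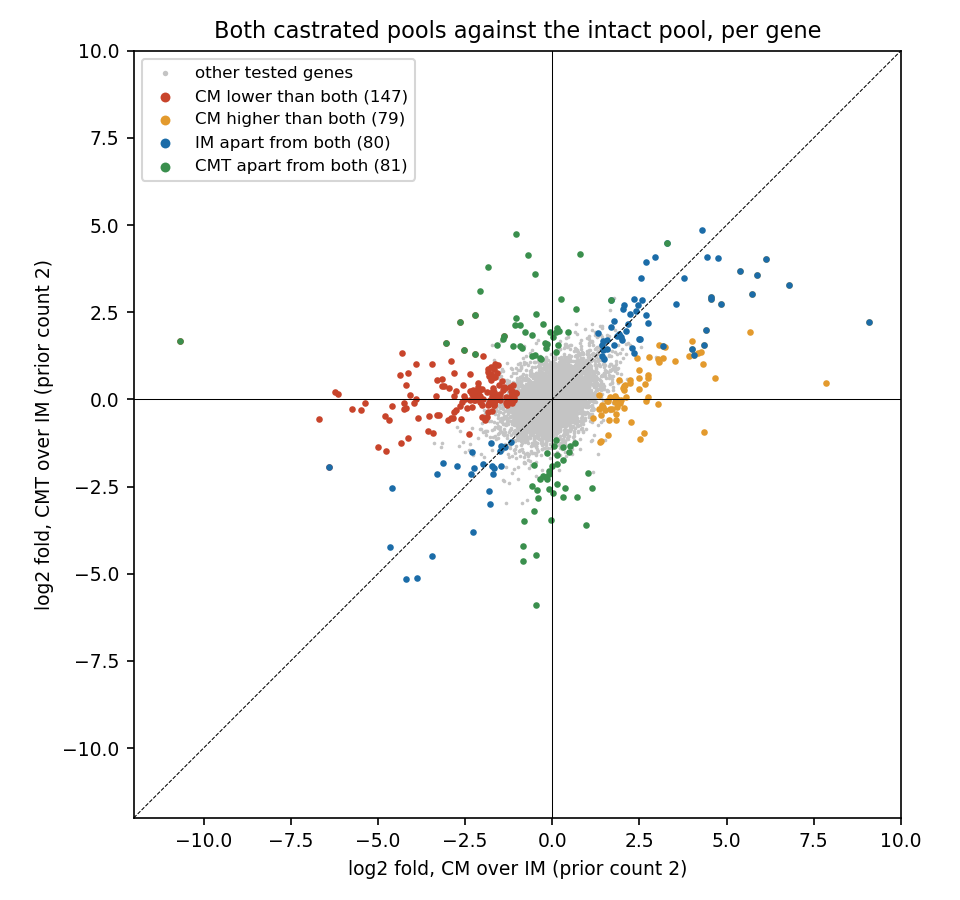
Each point is 1 of 15472 compared genes, with its log2 fold of CM over IM on the x axis and of CMT over IM on the y axis (prior count 2); the dashed line marks equal folds, and a gene in several coloured sets takes the colour listed last. The 147 genes with CM lower than both and the 79 with CM higher than both have median y values of 0.10 and 0.38, and the 80 genes with IM apart lie on the same side of 0 on both axes.

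**Figure D4:**
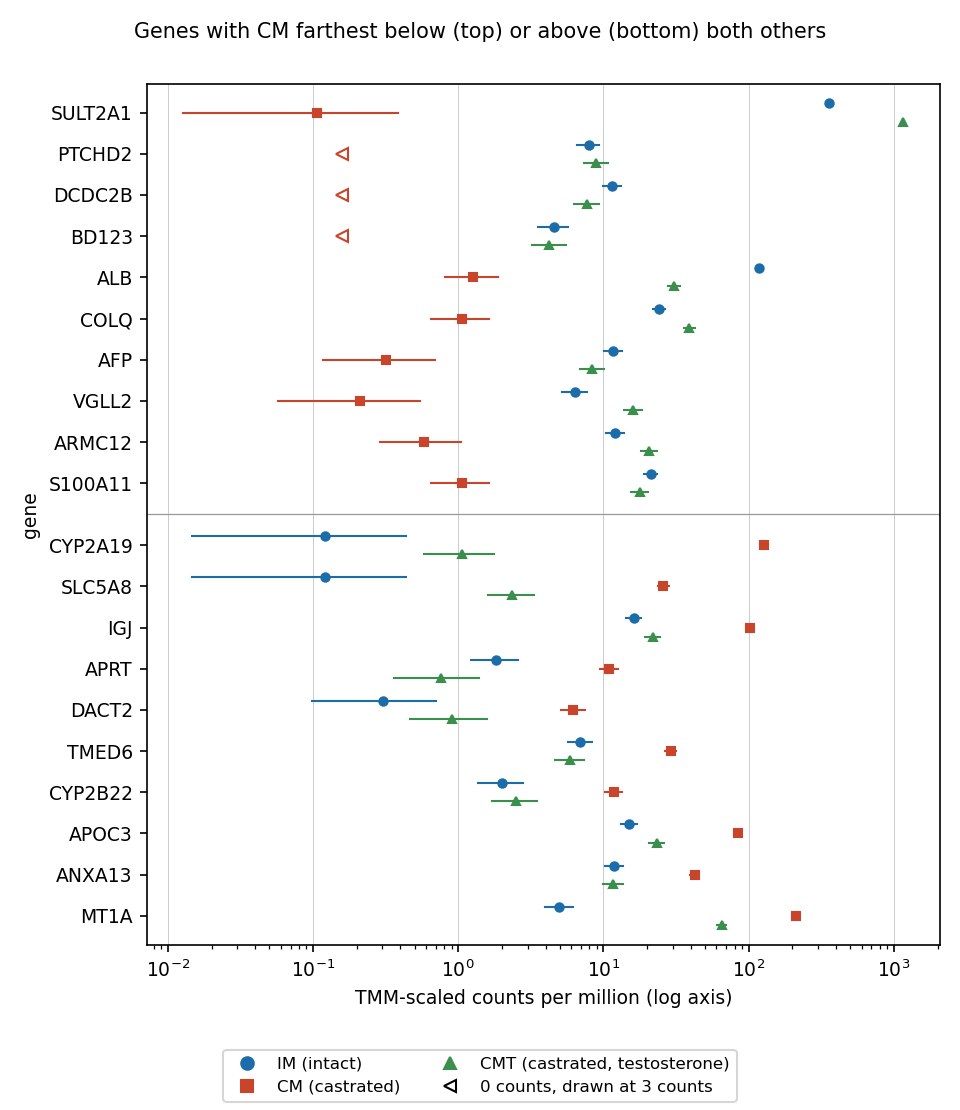
TMM-scaled CPM (log axis) of the 10 genes with CM farthest below both others and the 10 farthest above; symbols are the 3 pooled libraries, lines exact 95% Poisson counting intervals, and open triangles 0 counts drawn at 3 counts. ALB stands at 118 CPM in IM, 1.27 in CM and 30.5 in CMT, and APOC3 at 15.0, 84.2 and 23.2.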

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

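Counting mRNA genes only and ranking lists with deposited symbols only were tests chosen after seeing the data; all other alternatives were planned. No paired analysis was possible because each group is 1 pooled library, and for the same reason no replicate could be left out. Counts of called genes stayed within 1.5 times the reported ones under every scaling, without a filter, after thinning, without the most abundant genes and with mRNA genes only, and under the 99% interval except with CMT apart (53 genes). A mean CPM of at least 5, which tests fewer genes, gave 271 genes in CM against IM, 300 in CMT against CM, 132 in CMT against IM, 52 with IM apart and 44 with CMT apart. A threshold of 1.5-fold gave 963, 974, 579, 204 and 229 in that order and 500 with CM apart, and 4-fold gave 127, 130, 51, 19 and 19 and 73 with CM apart. CM stood apart in more genes than IM or CMT under each alternative. The balance of directions with CMT apart was 44 higher and 37 lower. It turned under total counts (36 and 41) and without the most abundant genes (40 and 44). Both of these settings scaled by plain totals. Under upper-quartile factors (44 and 37) and DESeq2 size factors (47 and 34) it held, so the balance depends on the scaling. Removal of abundant genes was not tested apart from the scaling. The share of the net variance carried by CM was 48.8% without a filter and 61.2% at a mean CPM of at least 5, where IM had 27.3% and 21.2% and CMT 23.9% and 17.6%; CMT had 24.3% with mRNA genes only. The cause was not tested for these shares. The lists standing apart in CMT against CM numbered 4 after thinning, with fewer counts behind each gene. Of the 29 list calls, 29 held under total counts, upper-quartile factors and DESeq2 size factors, and 21 held after thinning. Medians changed sign for adipocyte markers in CM against IM, without a filter (-0.11) and with deposited symbols only (-0.34), for that list in CMT against CM with deposited symbols only (0.36), and for P450 and conjugation enzymes in CMT against IM without a filter (-0.0093); the cause was not tested. Of the 183 calls of named genes, 176 held under total counts, 171 under the 99% interval and 93 at 4-fold, and none turned in direction under any of these. The rule can miss small folds. Simulated changes of 3-fold were called in 70% of genes in CM against IM, 76% in CMT against CM and 88% in CMT against IM.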

Other observations

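The counts of genes apart, the thinned counts and the shares of variance were planned; the tests of explanations that use them, and the tests on marker genes, on leukocyte lists and on CMT against IM in genes with CM apart, were chosen after the results were seen. Among genes that no list held, 2 without a symbol were abundant and far apart in CM, and were named after their values were seen. The noncoding gene LOC102165485 had 1167, 26963 and 1902 counts in IM, CM and CMT and was higher in CM than in IM by 20.2-fold (19.1 to 21.5). The mRNA gene LOC100627093 had 16696, 2122 and 19943 and was lower in CM than in IM by 8.98-fold (8.59 to 9.40). SAL1, the salivary lipocalin of the boar, set CMT apart from both other pools, at 10.4-fold (10.2 to 10.8) over CM, and its IM and CM levels were within 2-fold (1.72-fold, 1.64 to 1.80). The metallothionein genes differed in all 3 comparisons: MT1A, MT-2B and MT-III were lower in CMT than in CM by 3.27-fold (3.03 to 3.52), 3.17-fold (3.01 to 3.35) and 3.09-fold (2.69 to 3.57), yet remained higher than in IM by 13.1-fold (10.5 to 16.7), 7.46-fold (6.55 to 8.51) and 8.0-fold (5.67 to 11.6). CREB3L3 rose from IM to CM and again from CM to CMT (2.32-fold, 2.05 to 2.63).

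Levels in CMT were then set against IM for the genes in which CM lay apart from both, a choice that treats IM and CMT alike. The 147 genes lower in CM had a median log2 fold of CMT over IM of 0.10 (middle 50% of genes from -0.15 to 0.37), and 7 of them were called higher in CMT than in IM and 1 lower. The 79 genes higher in CM had a median of 0.38 (from -0.15 to 1.27), with 14 called higher and 0 lower. Among genes lower in CM, SULT2A1, HSD17B6, ACTC1 and PDK4 were called higher in CMT than in IM, and ALB was called lower.

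CM stood apart from both other pools in 226 genes, against 80 for IM and 81 for CMT. The deeper sequencing of CM is argued against, since thinning to the smallest library left 218 genes for CM and 77 for each of the others. Another share of nephron segments in the CM tissue is also argued against: over 7 lists of tubule, podocyte and endothelial markers, no median or quartile of the log2 fold of CM over IM lay farther than 0.36 from 0, short of the 2-fold change called in these genes. Smaller shifts are not excluded, since the distal convoluted tubule list (percentile 1.4) and the podocyte list (percentile 98.1) stood apart, as did stromal markers outside the 7 lists (lower quartile -0.46, percentile 1.29), and a shift within the proximal tubule was not tested. Low testosterone in CM, a chance difference between pools of pigs and the handling or preparation of the CM library cannot be told apart. Only 1 pool of castrated pigs without testosterone was sequenced, and handling and preparation were not tested. The share of net variance that CM carried, 54.7% and 48.8% without a filter, restates the pattern and decides for none of these.

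Some genes known from liver, muscle and adrenal cortex (ALB, AFP and PLG; ACTC1, COLQ, VGLL2 and the miscRNA row with the symbol TRDN; SULT2A1) were lower in CM than in IM, which carry-over of other tissue into the IM pool could produce. These were picked after their values were seen, and no list of them was tested. Other liver genes were higher in CM, such as APOC3 (5.60-fold, 4.89 to 6.42) and ASGR1 (at least 11.7-fold, interval from 9.07). Of the 7 measured adrenal cortex markers, 5 lay above 0 (median log2 fold of 0.29, percentile 96.9), so the pattern covers the named genes only. Tissue would bring its other abundant transcripts. In IM the summed counts of 11 such liver genes were 31, or 1.38% of the excess of ALB, AFP and PLG over CM, those of 14 muscle genes 12, or 0.44% of their excess, and those of 8 adrenal steroid genes 31, or 0.52% of that of SULT2A1. None of these markers reached a mean of 1 CPM; the most abundant in IM were FGA (17 counts), MYH7 (3) and HSD3B1 (14). These values argue against carry-over of each tissue, for the markers chosen. The liver share depends on that choice, since APOC3, which was not among the markers, had 249 counts in IM. It had more in CM (1591), the reverse of what carry-over into IM would give. Expression in kidney cells that differed between the pools for the named genes is the hypothesis left open, untested beyond these pools.

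The median of the interferon response list was higher in both castrated pools than in IM. Of its 58 genes, 5 were called higher in CM and 8 in CMT. Both comparisons use the single IM library, so an IM pool low in these genes by chance would give both. The castrated pools are therefore no independent repeat of each other. In CMT over CM the median log2 fold was 0.06, with 0 of 58 called. More leukocytes in those pools is a candidate explanation. In CMT over IM the interferon median exceeded that of lymphocyte markers by 0.76 on the log2 scale. The interquartile range of the lymphocyte genes was 0.63. Such a range is the spread between genes and not the error of a median, so it decides none of these questions. The lymphocyte list itself did not stand apart (median log2 fold of -0.002, percentile 61.2), with 16 of 32 genes above 0. That argues against a larger share of lymphocytes in CMT. The interferon median exceeded that of macrophage and granulocyte markers by 0.45, where their interquartile range was 0.70. These markers were high as a list too (median log2 fold of 0.31, percentile 99.99), though less than the interferon list. A larger share of these cells in CMT therefore cannot be told apart from a response in kidney cells. In CM over IM the gap to lymphocyte markers was 0.17 (interquartile range 0.84), and that to macrophage and granulocyte markers 0.39 (0.65). Lymphocyte markers stood apart there (median log2 fold of 0.34, percentile 99.93). Macrophage and granulocyte markers did not (median log2 fold of 0.12, percentile 92.0). Neither kind of leukocyte is excluded in CM. The interferon list shares 0 genes with either leukocyte list, but it includes antigen presentation genes such as CD74 and SLA-DRA. Sharing 0 genes therefore does not separate a response from leukocyte content. Infection or any other difference between the pooled pigs was not tested.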
